A study of Homo sapiens with 12 samples.

How the data were processed

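RNA was measured by bulk sequencing in 12 samples of stem cell-derived pancreatic alpha cells, which were differentiated from HUES-8, an established human embryonic stem cell line. The labels give 6 samples treated with DMSO and 6 treated with tunicamycin, numbered 1 to 6 in each group as biological replicates. Samples numbered 1 to 3 form sequencing batch 1 and samples numbered 4 to 6 form batch 2, so each batch holds 3 samples of each group. Total RNA was isolated with a column kit (Qiagen RNeasy Mini) and libraries were made with NEBNext Ultra II RNA chemistry, per the labels' protocols.

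The deposited table holds raw read counts, as whole numbers, for 28278 gene symbols in the 12 samples, with no normalization. Per the submitters' processing notes, cutadapt 4.4, HISAT2 2.1.0 and featureCounts 2.0.6 were used with the GRCh38 genome build. The strand setting of the counting and the gene annotation are not given in the sources used here, so counts of genes that overlap another gene or have an antisense partner are uncertain. Counts of near-identical genes are uncertain as well, among them LEFTY1, PRSS1, PRSS2, CELA3A, CELA3B, FTL, FTH1 and the ribosomal protein genes. Gene positions were taken from GENCODE release 29 for GRCh38 and may differ from the annotation used in counting.

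Totals per sample ran from 17523442 to 28872269 counts. Confidence intervals of a share of counts are 95% exact binomial intervals and cover counting error only, because reads without molecular identifiers are not independent molecules. Every pair of samples within a group differed by more than sampling noise, with a chi-square per gene of 10.9 to 99.6 over genes with a summed count of 20 or more, so all 12 samples were counted separately. Whether the biological replicates came from separate differentiations is not given in the sources used here, so p-values measure the spread between these samples.

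Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 17137 genes and removed 11141. Library sizes were scaled with TMM factors, and expression is given as CPM, computed from the scaled library sizes. The comparison of tunicamycin with DMSO used edgeR's quasi-likelihood test with batch as a covariate and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p and no minimum fold. Whether the response differed between batches was tested with the interaction of treatment and batch. All p-values are two-sided, and adjusted p-values of single genes are from edgeR unless another tool is named. Fold changes are tunicamycin over DMSO with the standard error of the log2 value, and CPM values are mean ± SD of 6 samples.

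Gene lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with adjustment over the lists tested. A total of 33 lists with 774 members were fixed before the data were examined. The list of 13 mitochondrially encoded genes was not analysed here, so 32 lists were tested. For 1 member an older symbol was used. Genes were named by a rule also fixed before the data were examined. It takes 16 genes of interest and the 6 largest changes in each direction among called genes with a mean log2 CPM of 3 or more, whose samples did not overlap within either batch. It adds up to 3 called members of each list with a mean log2 CPM of 1 or more, and the 5 genes with the smallest interaction p. Where no member of a list was called, its 2 most abundant members were taken. The main design, the test and the alternatives were fixed at that time too, except 7 gene lists and 2 alternative fits that were added after seeing the data and are identified as such where they appear.

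Equal numbers in both groups were found to pair the samples. The deviations from the group and batch means of samples with the same number correlated across genes at 0.50, 0.58, 0.52, 0.12, 0.18 and 0.18 for numbers 1 to 6, and the highest correlation with another number was -0.02. Deviations from a mean of 3 samples sum to 0, which pushes correlations with other numbers below 0. From the group means the same-number correlations were 0.40, 0.61, 0.61, 0.36, 0.39 and 0.11. The highest with another number was then 0.28 (number 5), and for number 6 it was 0.06. The labels do not say what a number marks. Fits with the number as a block are therefore given beside a result where they change a call or move a count by over 1.5 times.

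The tests were tried on simulated counts with 200 changed genes among 16921. The main test recovered 43.3% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold, with 5.2% of 155 calls false. With the block these shares were 26.9%, 74.6% and 98.5%, with 5.7% of 141 calls false. Simulated samples were drawn independently, without pairs, so the shares do not show how the tests perform on paired samples. The interaction test, simulated on 16907 genes, recovered 4.5% of genes whose response differed 1.5-fold or 2-fold and 72.7% of those that differed 4-fold, with 5.3% of 57 calls false. Camera recovered 20 of 20 lists shifted 1.4-fold and called 0 simulated lists without a shift. On the real libraries, other groupings of the samples moved a median of 12 and at most 22 lists at the same preset correlation, so the simulated lists do not give its rate of false calls there. Many of those groupings hold part of the treatment difference, so they do not give that rate either. Groupings that share 6 of the 12 samples with the real one or its mirror have equal numbers of both groups on each side. They still moved between 3 and 15 lists, so the preset correlation calls lists on these libraries without a net treatment difference. With no simulated effect the main test called 0 of 17137 genes.

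Alternatives were other scaling factors (RLE, upper quartile, totals alone), the tests of DESeq2 1.42.0 and limma-voom, other filters on low counts, no batch covariate, the block, each batch alone, each sample left out in turn, stricter thresholds, and for lists an estimated correlation and fry. The fits added later left out both samples numbered 1, or took the mean of the mesenchymal list as a covariate. XIST and Y-linked genes were left out of named results, and some genes that the naming rule selects are not reported here.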

Results

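Alpha cells are the glucagon-secreting cells of the pancreatic islet. Alpha cells derived from the embryonic stem cell line HUES-8 were kept in bioreactors of 30 mL, turning at 40 rpm, for 48 h with the solvent DMSO or with 5 uM tunicamycin. Tunicamycin inhibits the first step of N-glycan assembly, which is catalysed by DPAGT1, and thereby causes unfolded protein to build up in the endoplasmic reticulum (ER). The comparison asked how ER stress alters gene expression in these cells, as a model of alpha cell dysfunction in diabetes. Transcripts were counted in 6 DMSO and 6 tunicamycin samples, 3 of each group in each of 2 sequencing batches. Libraries held 23.3 ± 4.47 M counts in the DMSO group and 22.2 ± 1.70 M in the tunicamycin group (SD, n = 6 each). Genes with at least 1 count numbered 20320 ± 363 and 19959 ± 501. A single transcript, GCG, which encodes glucagon, took between 4.77% of counts (tunicamycin 1, 95% exact binomial interval 4.76 to 4.78%) and 8.79% (DMSO 2, 8.77 to 8.80%).

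Of the 6 largest called increases among abundant genes 4 were genes of ER protein folding, and the largest called decreases were those of ID1 and ID3. HSPA5, the main ER chaperone (BiP; chromosome 9, 125234853 to 125241330, minus strand, GRCh38), rose 6.19-fold, from 845 ± 144 to 5270 ± 1022 CPM (log2 fold change 2.63 ± 0.16, adjusted p = 3.7e-07). The ER chaperone HSP90B1 rose from 867 ± 128 to 5370 ± 804 CPM (log2 fold change 2.63 ± 0.14, adjusted p = 1.2e-07), and PDIA4, a disulfide isomerase, and MANF, an ER-resident secreted factor, rose by similar amounts (2.59 and 2.56 on the log2 scale). NIBAN1 (chromosome 1, 184790724 to 184974550, minus strand) rose 10.1-fold, from 3.0 ± 1.1 to 30.3 ± 8.1 CPM (adjusted p = 4.9e-06), and SLC18A2, the vesicular monoamine transporter, rose 7.19-fold (adjusted p = 3.4e-05). ID1, a transcriptional inhibitor induced by BMP signalling (chromosome 20, 31605283 to 31606515, plus strand), fell from 271 ± 87 to 16.8 ± 7.8 CPM (log2 fold change -4.02 ± 0.30, adjusted p = 2.1e-06). Its relative ID3 (-2.99 ± 0.38), the Nodal antagonist LEFTY1 (-2.48 ± 0.38), the calcium-binding protein gene CALB1 (-2.38 ± 0.25), the plasminogen activator gene PLAT (-2.35 ± 0.44) and CAPN6 (-2.34 ± 0.46) also fell, with adjusted p between 4.4e-05 and 0.0067. Each of these 12 genes moved in 1 direction in 6 of 6 pairs of samples with the same number, which the naming rule fixes in advance. It takes only genes whose groups do not overlap within either batch, and each pair lies within a batch. Tunicamycin 3 was the lowest of its group for NIBAN1, at 15.8 CPM, and tunicamycin 2 for CAPN6, at 0.317 CPM. With the mean of mesenchymal markers as a covariate, a fit added after seeing the data, the change of PLAT was -1.47.

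In all, tunicamycin changed 1344 of 17137 genes (7.84%), of which 781 rose and 563 fell. A change of at least 2-fold was seen in 411 of them, 218 higher and 193 lower. The block for sample number gave 2967 changed genes, 1528 higher and 1439 lower, and contained all 1344 in the same direction. Without tunicamycin 4 the count was 791, with 514 higher and 277 lower. The count of lower genes was also reduced to 355, 344 and 332 without DMSO 1, DMSO 5 and tunicamycin 5, respectively.

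**Figure D1:**
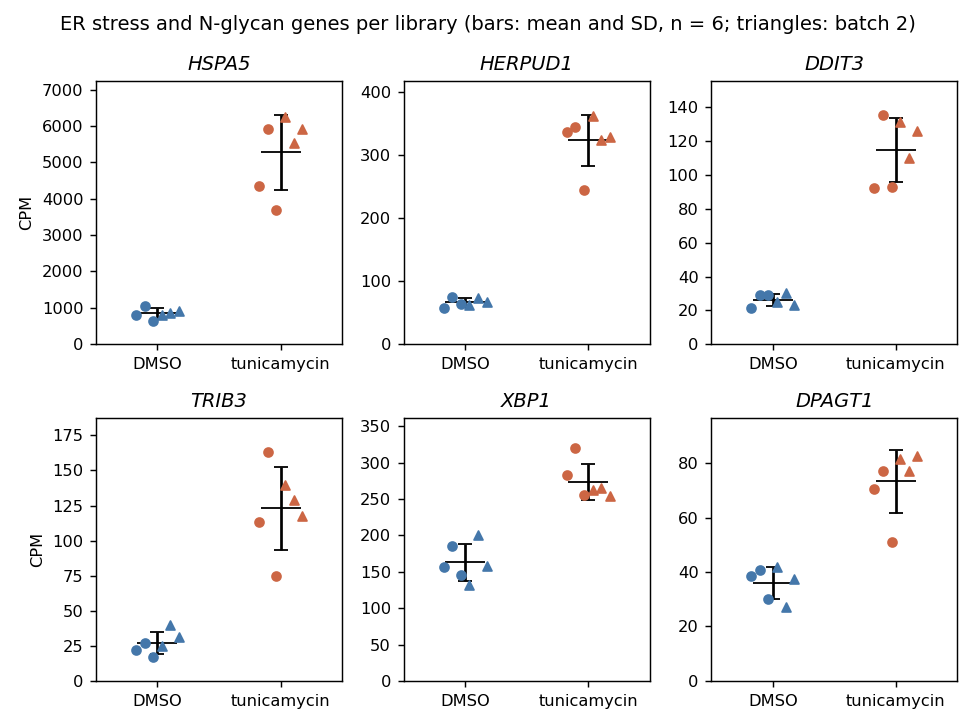
Expression in CPM (linear axes from 0) of 6 ER stress and N-glycan genes in each DMSO and tunicamycin library, with circles for batch 1, triangles for batch 2, and bars for the mean and SD of 6 libraries. Every tunicamycin library lies above every DMSO library in each panel, with means for HSPA5 of 845 and 5270 CPM and for XBP1 of 163 and 273 CPM.

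Most measured genes of the ER folding machinery rose. Among ER chaperones and folding enzymes, 21 of 24 tested members rose and 0 fell, or 23 and 0 when adjusted over the list alone. DNAJB11, CRELD2 and DNAJB9 rose by 2.24, 2.26 and 2.31 on the log2 scale, and the median of the list was 1.68 (1.65 in batch 1 and 1.69 in batch 2, camera adjusted p = 5.37e-142). In ER-associated degradation, which returns misfolded proteins to the cytosol, 11 of 23 members rose and 0 fell (15 and 0 adjusted over the list alone). HERPUD1 rose from 66.6 ± 6.8 to 324 ± 41 CPM, with tunicamycin 3 lowest at 245 CPM, and SEL1L and SYVN1, which form the core of the HRD1 ubiquitin ligase, rose by 1.99 and 1.61. The median of that list was 0.50 (0.39 and 0.63 in batches 1 and 2, adjusted p = 2.94e-32). Genes of translocation into the ER and of vesicle transport had 22 of 42 members higher and 0 lower (27 and 1 adjusted over the list alone, 25 and 1 with the block). They included SPCS3 of the signal peptidase (1.20), SEC63 of the translocation channel (1.10) and SSR3 of the translocon-associated complex (1.11), and the median was 0.40 (0.33 and 0.49, adjusted p = 2.07e-27).

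Some genes of N-glycan synthesis, the process that tunicamycin blocks, rose as well. Of 36 members 16 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.46 (0.42 in each batch, adjusted p = 9.04e-26). DPAGT1, which encodes the target of the drug, rose 2.03-fold, from 35.9 ± 6.0 to 73.3 ± 11.7 CPM (log2 fold change 1.02 ± 0.14, adjusted p = 0.00036), with tunicamycin 3 lowest at 51.0 CPM. ALG5, a glucosyltransferase of the pathway, rose by 1.40, MAGT1, an oxidoreductase subunit of the oligosaccharyltransferase, by 1.55, and UGGT1, the folding sensor that reglucosylates glycoproteins, by 1.22. The hexosamine pathway supplies the sugar donor for this synthesis and for O-GlcNAc. Of its 8 genes 4 rose and 0 fell (6 and 0 adjusted over the list alone), among them GFPT1 (1.00), PGM3 (0.80) and OGT (0.66), and the median was 0.48 (0.50 and 0.48, adjusted p = 1.04e-05).

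Some sensors and regulators of the unfolded protein response rose too. Of 15 sensors and regulators, 7 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.44 (0.47 and 0.42, adjusted p = 1.47e-12). ERN1, which encodes the sensor IRE1, rose by 1.90, EIF2AK3, which encodes PERK, by 1.09 and CREB3L2 by 0.98. XBP1 rose from 163 to 273 CPM (0.74 ± 0.11, adjusted p = 0.00095). The rise of ATF4, from 451 ± 77 to 621 ± 86 CPM (0.46 ± 0.11, adjusted p = 0.022), was not called without DMSO 4 (adjusted p = 0.0538), without tunicamycin 4 (0.0582), without the batch covariate (0.0604) or with the mesenchymal mean as a covariate (0.0896).

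Targets of the transcription factors ATF4 and CHOP rose as a group. Of 35 tested, 27 rose and 0 fell (32 and 0 adjusted over the list alone), with a median of 1.16 (1.09 in batch 1 and 1.16 in batch 2, adjusted p = 1.54e-47). DDIT3, which encodes CHOP, rose 4.37-fold, from 26.2 ± 3.7 to 115 ± 19 CPM (adjusted p = 4.1e-07). TRIB3, a pseudokinase induced by CHOP, rose by 2.21 ± 0.19 (adjusted p = 8.3e-06) and SLC7A11, the cystine importer, by 2.39 ± 0.23 (adjusted p = 1.8e-05). Among cytosolic aminoacyl-tRNA synthetases, 10 of 20 rose and 0 fell (12 and 1 adjusted over the list alone), including WARS1 (1.75), IARS1 (1.19) and SARS1 (0.83). The median of the synthetases was 0.34 (0.39 and 0.30, adjusted p = 5.00e-08), and this call was lost with an estimated correlation (adjusted p = 0.0533).

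**Figure D2:**
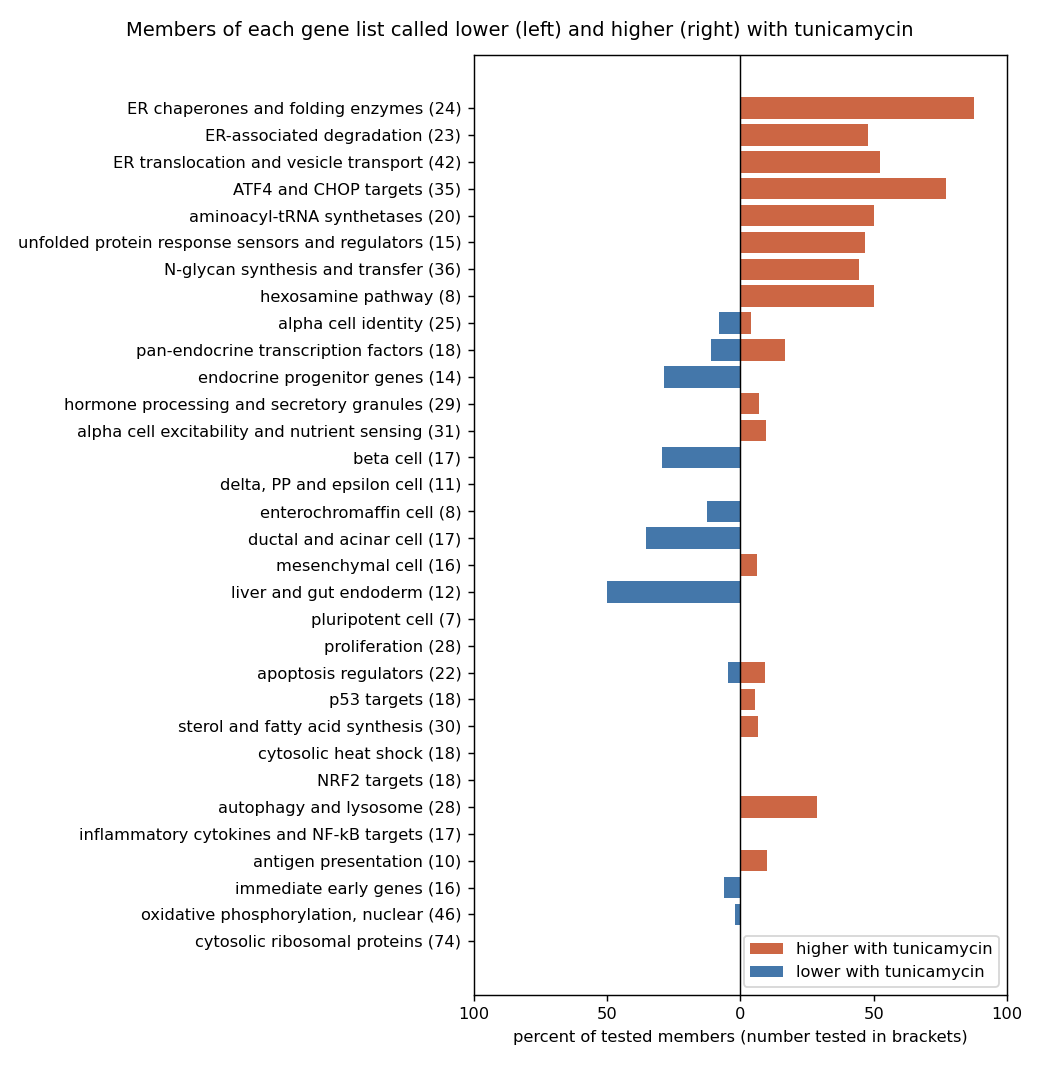
Percent of the tested members of each gene list called lower (bars to the left) or higher (bars to the right) with tunicamycin at an edgeR adjusted p under 0.05 over all genes, with the number tested in brackets. The bars reach furthest for ER chaperones (21 of 24 higher) on the right and for liver and gut markers (6 of 12 lower) on the left.

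The glucagon transcript itself did not pass the test. GCG (chromosome 2, 162142873 to 162152404, minus strand) stood at 74634 ± 14010 CPM with DMSO and 56820 ± 7797 CPM with tunicamycin (log2 fold change -0.39 ± 0.16, adjusted p = 0.176). It was lower in 6 of 6 pairs, with -0.44 in batch 1 and -0.33 in batch 2, and DESeq2 called it (adjusted p = 0.038). The alpha cell transcription factor gene IRX2 (-0.22, adjusted p = 0.27), the glucagon-processing protease gene PCSK2 (-0.17, adjusted p = 0.75) and TTR (-0.13, adjusted p = 0.73) did not pass either. Over the alpha cell identity list 1 of 25 members rose and 2 fell, the same numbers as adjusted over the list alone, against 3 and 3 with the block. CRYBA2, a crystallin gene enriched in alpha cells, fell from 630 ± 154 to 179 ± 43 CPM (-1.80 ± 0.20, adjusted p = 7.6e-05). It was lowest among DMSO libraries in DMSO 6, at 335 CPM. SMOC1 was the member that rose (0.43, adjusted p = 0.018), a call lost without tunicamycin 4 (0.0588) and with the mesenchymal mean as a covariate (0.0792). The list median was -0.10 (-0.19 and -0.02 in batches 1 and 2, adjusted p = 0.241). The list was called lower without tunicamycin 2 (median -0.21, adjusted p = 0.0371) and with the mesenchymal covariate (-0.22, adjusted p = 0.0046). Over the 12 fits that left out a sample its median ran from -0.21 to 0.035, with a highest adjusted p of 0.669.

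**Figure D3:**
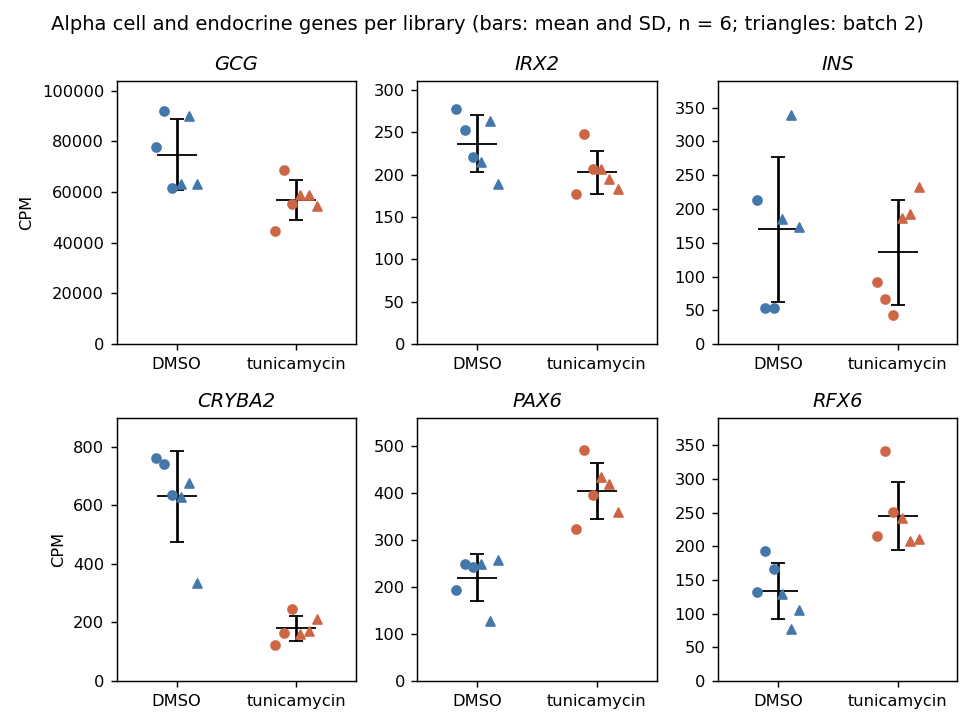
Expression in CPM (linear axes from 0) of 6 alpha cell and endocrine genes in each library, with circles for batch 1, triangles for batch 2, and bars for the mean and SD of 6 libraries. GCG overlaps between groups (74634 and 56820 CPM), while CRYBA2 is lower (630 and 179 CPM) and PAX6 higher (220 and 404 CPM) in every tunicamycin library than in any DMSO library.

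Transcription factors shared by islet cells moved in both directions. Of 18, 3 rose and 2 fell (4 and 2 adjusted over the list alone). PAX6 rose from 220 ± 51 to 404 ± 59 CPM (0.88 ± 0.17, adjusted p = 0.0048), RFX6 by 0.90 and MLXIPL, which encodes the glucose-responsive factor ChREBP, by 0.79. The members that fell were FOXA2 (-0.38, adjusted p = 0.031) and HNF4A (-0.47, adjusted p = 0.0499), named after their values were seen. The list median (-0.09) and the test, which pointed up (adjusted p = 0.320), differed in sign.

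Of 14 genes of endocrine progenitors 0 rose and 4 fell (0 and 6 adjusted over the list alone). PAX4, which acts during islet cell specification, fell by 1.31 ± 0.27 on the log2 scale (adjusted p = 0.0084). NEUROG3, the inducer of endocrine fate and named after its values were seen, was lower at 3.87 ± 1.71 against 8.98 ± 4.23 CPM (-1.16, adjusted p = 0.0397). FEV (-0.64, adjusted p = 0.026) and GP2 (-0.97, adjusted p = 0.038) were called as well. The call of FEV was lost without DMSO 1 (0.0602), tunicamycin 4 (0.0728), DMSO 5 (0.0641) or tunicamycin 5 (0.0531), and that of GP2 without DMSO 1, DMSO 2, tunicamycin 2, DMSO 4, tunicamycin 4, DMSO 5 or tunicamycin 5 (0.0514 to 0.103), with limma-voom (0.0545) and without the batch covariate (0.0602). With the mesenchymal covariate both were lost (0.0711 and 0.127). The list median was -0.43 (-0.30 and -0.60, adjusted p = 0.0017), or -0.79 without tunicamycin 1, and the call was lost with an estimated correlation (adjusted p = 0.0533).

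Secretory granule and excitability genes showed few calls. For hormone processing and secretory granules, 2 of 29 members rose and 0 fell, the same numbers as adjusted over the list alone, and 9 and 0 with the block. They were CPLX1, which encodes a complexin, a regulator of vesicle fusion (0.49, adjusted p = 0.0098), and the synaptotagmin gene SYT4 (0.92, adjusted p = 0.015). Both calls were lost with the mesenchymal covariate (0.0505 and 0.0618). The list median was 0.18 (0.21 and 0.19, adjusted p = 0.0115), and the list call was lost with an estimated correlation (adjusted p = 0.740). It was also lost without tunicamycin 2 (median 0.10, adjusted p = 0.132), without DMSO 3 (0.0579) and with the mesenchymal covariate (median 0.06, adjusted p = 0.808). Of 31 excitability and nutrient-sensing genes 3 rose and 0 fell, against 6 and 1 adjusted over the list alone and 8 and 5 with the block. INSR, which encodes the insulin receptor, rose by 0.68 (adjusted p = 0.00057), with tunicamycin 1 lowest of its group at 122 CPM. FFAR1, a fatty acid receptor gene, was called (0.70, adjusted p = 0.032), but not without DMSO 1, tunicamycin 2, DMSO 3, DMSO 4, tunicamycin 4, DMSO 5, tunicamycin 5 or DMSO 6 (0.0508 to 0.0848) or with the mesenchymal covariate (0.0797). The list did not move as a whole (median 0.10, 0.11 and 0.02 in batches 1 and 2, adjusted p = 0.320).

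Some markers of beta cells fell, while insulin itself did not pass the test. Of 17 beta cell genes 0 rose and 5 fell, against 1 and 7 both adjusted over the list alone and with the block. They included SAMD11 (-1.60), PDX1 (2.01-fold lower, adjusted p = 0.0030) and NKX6-1 (-0.69, adjusted p = 0.0094), the latter both transcription factors of beta cell identity. HADH (-0.43) and IAPP, which encodes amylin (-0.80), complete the 5 and were named after their values were seen. INS was at -0.43 ± 0.33 (adjusted p = 0.49). The median of the list was -0.43 (-0.45 and -0.28, adjusted p = 0.00039), or -0.24 without both samples numbered 1. No member of the list for delta, PP and epsilon cells passed over all genes (0 and 0 of 11, 0 and 1 adjusted over the list alone and with the block). Somatostatin, SST, was at 0.10 (adjusted p = 0.88; 0.56 in batch 1, -0.36 in batch 2) and ETV1 at -0.17, and the list median was -0.26 (-0.14 and -0.40, adjusted p = 0.241; 0.0455 in batch 2 alone). For enterochromaffin cells, 0 of 8 genes rose and 1 fell, the serotonin-synthesis gene DDC (-0.69, adjusted p = 0.011), against 1 and 3 both adjusted over the list alone and with the block. The median of these genes was -0.34 (-0.53 and 0.02, adjusted p = 0.198).

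Some markers of ductal, acinar, liver and gut cells fell. Of 17 ductal and acinar genes 0 rose and 6 fell (0 and 10 adjusted over the list alone), including the chloride channel gene CFTR (-1.43, adjusted p = 0.0015), the keratin gene KRT19 (-0.77, adjusted p = 0.0023) and the acinar factor PTF1A (-1.51, adjusted p = 0.0055). Of 12 liver and gut genes 0 rose and 6 fell (0 and 8 adjusted over the list alone), including ALB (-2.10, adjusted p = 0.0017), AFP (-1.97, adjusted p = 0.0048) and VIL1 (-0.57, adjusted p = 0.016). The medians were -0.77 (-0.90 and -0.69, adjusted p = 2.08e-06) and -0.75 (-0.87 and -0.53, adjusted p = 1.79e-06). Both calls were lost with an estimated correlation (adjusted p = 0.0533 for each).

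Mesenchymal markers varied between libraries. COL1A1, a collagen gene, was at 432 CPM in DMSO 1 and 98.2 CPM in tunicamycin 1, and at 154 and 158 CPM in the samples numbered 5. Of 16 members 1 rose and 0 fell (1 and 1 adjusted over the list alone), but 1 rose and 11 fell with the block. The member that rose was TAGLN, an actin-binding protein gene (1.32 ± 0.19, adjusted p = 0.0006). The median was -1.09 (-1.45 in batch 1 and -0.42 in batch 2, where adjusted p = 0.132; both batches together 0.0220). The call was lost with an estimated correlation (adjusted p = 0.740) and without DMSO 1 (median -0.56, adjusted p = 0.127), tunicamycin 2 (0.119) or DMSO 3 (0.0575). No pluripotency gene passed (0 and 0 of 7, also adjusted over the list alone), with SOX2 at 0.41, highest in DMSO 1 at 42.0 CPM, and TERF1 at -0.03. The median of the pluripotency list was -0.29 (-0.31 and 0.03, adjusted p = 0.488).

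**Figure D4:**
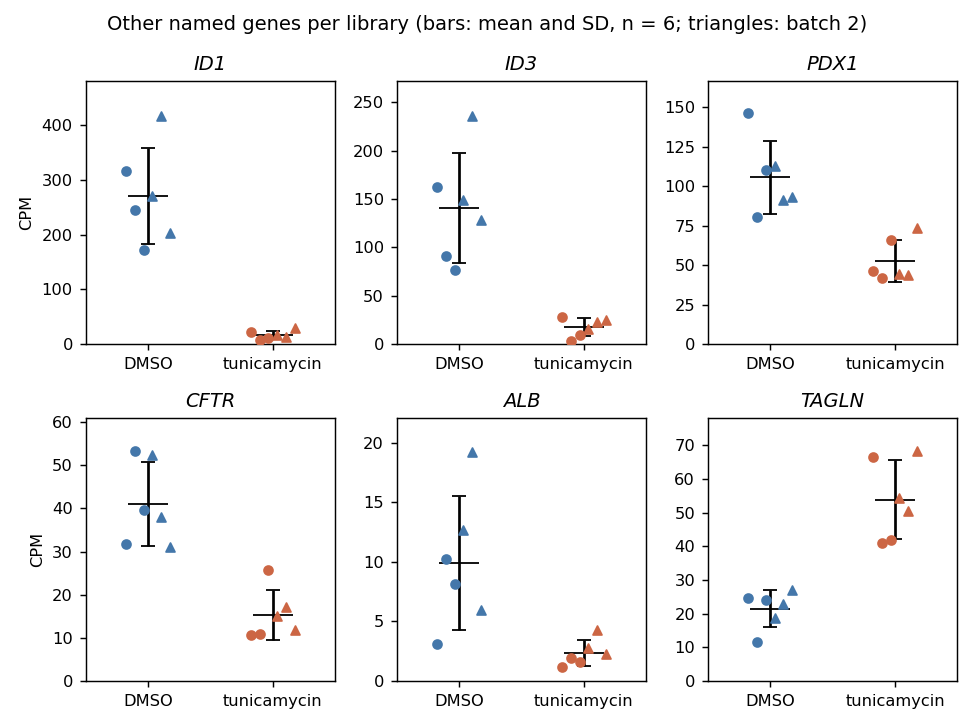
Expression in CPM (linear axes from 0) of ID1, ID3, PDX1, CFTR, ALB and TAGLN in each library, with circles for batch 1, triangles for batch 2, and bars for the mean and SD of 6 libraries. ID1 averages 271 CPM with DMSO and 16.8 CPM with tunicamycin, TAGLN is the panel that is higher with tunicamycin, and the groups overlap for ALB.

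Proliferation genes did not pass (0 and 0 of 28, also adjusted over the list alone), against 0 and 3 with the block. TOP2A was at -0.36 (adjusted p = 0.32, with the block 0.022) and MCM7 at 0.07. The median was -0.16 (-0.15 and -0.23, adjusted p = 0.109). The list was called lower with the block (0.0488) and without tunicamycin 1, DMSO 2 or DMSO 4 (0.0105 to 0.0167). With 1 sample left out its median ran from -0.26 to -0.04, and the highest adjusted p was 0.629. Apoptosis regulators were mixed, with 2 of 22 higher and 1 lower, 2 and 3 adjusted over the list alone and 4 and 3 with the block. BIK, a BH3-only gene, fell (-1.57 ± 0.12, adjusted p = 3.7e-06) and BBC3, which encodes the BH3-only protein PUMA, rose (0.90, adjusted p = 0.0036). The death receptor gene TNFRSF10B was called higher (0.66, adjusted p = 0.025), but not without tunicamycin 4, DMSO 5 or tunicamycin 5 (0.0531 to 0.0609). The median of that list was 0.01 and the test pointed down (adjusted p = 0.803). Of 18 p53 targets 1 rose over all genes (TP53INP1, 0.42, adjusted p = 0.0499), 0 rose or fell adjusted over the list alone, and 1 rose and 2 fell with the block. TP53INP1 kept its call only without tunicamycin 1 or DMSO 3 among the 12 fits that left out a sample (otherwise 0.0505 to 0.119), and lost it under each other scaling (0.0523 to 0.0646), with limma-voom (0.0538), with no filter on low counts (0.0563), without the batch covariate (0.225) and with the mesenchymal covariate (0.193). The list median was -0.03 (adjusted p = 0.996).

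Of 28 autophagy and lysosome genes 8 rose and 0 fell, against 12 and 0 adjusted over the list alone and 13 and 0 with the block. ATG13 of the autophagy initiation complex rose by 0.81, the ubiquitin-like modifier gene GABARAPL1 by 0.85 and the lysosomal channel gene MCOLN1 by 0.63. The median was 0.23 (0.24 in each batch, adjusted p = 2.08e-06; 0.11 with the mesenchymal covariate), and the call was lost with an estimated correlation (adjusted p = 0.329). Sterol and fatty acid synthesis had 2 of 30 members higher and 0 lower, the same adjusted over the list alone, against 4 and 3 with the block. They were the sterol carrier gene STARD4 (0.82) and HSD17B7 (0.49). Its median was 0.0014 (0.07 and -0.14, adjusted p = 0.905), slightly below 0 with RLE factors (-0.0037) and -0.20 (adjusted p = 0.0019) with the mesenchymal covariate.

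Other stress programmes held few or no called members. Cytosolic heat shock genes had 0 and 0 of 18, also adjusted over the list alone, and 0 and 2 with the block. HSP90AB1 was at -0.02 and HSP90AA1 at -0.33 (adjusted p = 0.29, with the block 0.047), with DMSO 3 and tunicamycin 3 lowest of their groups for HSP90AA1, at 624 and 564 CPM. The heat shock median was -0.17 (-0.15 and -0.13, adjusted p = 0.103). That list was called lower without tunicamycin 2 (0.0212), DMSO 3 (0.0034) or tunicamycin 4 (0.0394) and with the mesenchymal covariate (0.0054). Its median ran from -0.23 to -0.04 with 1 sample left out, and the highest adjusted p was 0.372. NRF2 targets of the oxidative stress response had 0 and 0 of 18, also adjusted over the list alone, and 1 and 4 with the block. The ferritin genes FTL (-0.41, adjusted p = 0.38, with the block 0.046) and FTH1 (-0.06) stand for them, and their median was -0.09 (-0.10 and -0.14, adjusted p = 0.320), called with the mesenchymal covariate (median -0.23, adjusted p = 0.0296).

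Inflammatory genes had 0 and 0 of 17, also adjusted over the list alone, and 2 and 2 with the block, with SOD2 at -0.09 and NFKB1 at 0.03. Their median (0.03) and the test, which pointed down (adjusted p = 0.905), differed in sign. For antigen presentation 1 of 10 rose, in all 3 countings, namely the ER aminopeptidase gene ERAP1 (0.94, adjusted p = 0.0092), with a median of 0.07 (adjusted p = 0.417). Immediate early genes had 0 of 16 higher and 1 lower, against 3 and 5 adjusted over the list alone and 2 and 3 with the block. The lower gene was JUNB (-0.71, adjusted p = 0.022), not called without tunicamycin 3, DMSO 5 or tunicamycin 5 (0.0508 to 0.0659) or without the batch covariate (0.0572). The median of these genes was -0.32 (-0.40 and -0.19, adjusted p = 0.357).

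Nuclear genes of oxidative phosphorylation and ribosomal protein genes had medians slightly below 0. For oxidative phosphorylation the median was -0.26 (-0.24 and -0.28, adjusted p = 8.69e-07), or -0.17 without DMSO 5, with 45 of 46 members below 0. The call was lost with an estimated correlation (adjusted p = 0.529) and with fry (0.099). Over all genes 0 members rose and 1 fell (0 and 0 adjusted over the list alone), against 0 and 7 with the block. The lower gene was ATP5PO of the ATP synthase (-0.45, adjusted p = 0.038). It was not called without DMSO 1, tunicamycin 1, tunicamycin 2, tunicamycin 3, tunicamycin 4, DMSO 5, tunicamycin 5 or tunicamycin 6 (0.0516 to 0.0943), without the batch covariate (0.0681) or with the mesenchymal covariate (0.165). Ribosomal protein genes had 0 and 0 of 74, also adjusted over the list alone, with RPL3 at -0.16 and RPL13A at -0.21. Their median was -0.19 (-0.22 and -0.13, adjusted p = 0.00050), with 71 of 74 below 0. It was -0.09 without DMSO 1 (adjusted p = 0.0761) and -0.10 without DMSO 5 (0.0918), where the call was lost, as it was with an estimated correlation (adjusted p = 0.740) and with fry (0.396).

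Of the 32 lists tested, 17 moved. At the same preset correlation, groupings with equal numbers of both groups on each side moved between 3 and 15 lists. With an estimated correlation 8 calls held, those for ER chaperones, ER-associated degradation, translocation and transport, ATF4 and CHOP targets, sensors and regulators, N-glycan synthesis, the hexosamine pathway and beta cells, and 9 were lost.

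The second comparison asked whether the response differed between the sequencing batches. No gene passed the interaction test in edgeR (0 genes, lowest adjusted p 1.00), in DESeq2 (0, lowest 0.187), in limma-voom (0) or in edgeR with the block (0). At an unadjusted p under 0.05 these tests gave 169, 191, 132 and 458 genes, where 5% of the tested genes would be 857. Counts this far below 5% mean that the tests were conservative here. In simulated samples without pairs the edgeR interaction test recovered 4.5% of 2-fold differences. The lack of calls therefore does not show that the batches responded equally. Genes with the smallest interaction p were EEF1D (log2 fold change -2.87 in batch 1 and 0.79 in batch 2), DENND2B (-0.60 and -0.10), PDE2A (-0.49 and 0.62), HPGD (1.01 and -0.36) and MTRR (0.06 and 0.56). EEF1D was highest among tunicamycin libraries in tunicamycin 6, at 14.2 CPM. In batch 1 it stood at 35.2 CPM in DMSO 1 and 27.3 CPM in DMSO 2, but at 2.21 CPM in DMSO 3, against 2.94 CPM in tunicamycin 3. In batch 1 alone 57 of 16940 genes passed, 51 higher and 6 lower, and in batch 2 alone 654 of 16634, 449 higher and 205 lower. All 57 genes of batch 1 had the same sign in batch 2, where 55 were called, and 642 of the 649 genes of batch 2 that were tested in batch 1 had the same sign there. The log2 fold changes of HSP90B1 were 2.57 and 2.69 in the 2 batches, those of DDIT3 2.03 and 2.24, and those of ID1 -4.12 and -3.91.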

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

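In 17 of 272 sets of 6 samples, 1 sample lay farther from the others than Dixon's test allows, where chance alone gives about 5%. Values are CPM for genes and mean log2 CPM for gene lists, each with the nearest other sample of its group.

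Tunicamycin 3 accounts for 6 of the 17 and lay lowest in each. It had 245 CPM of HERPUD1 (nearest 324), 51.0 of DPAGT1 (nearest 70.5), 15.8 of NIBAN1 (nearest 30.0) and 564 of HSP90AA1 (nearest 850). For the lists its means were 5.62 for ATF4 and CHOP targets (nearest 6.05) and 6.40 for sensors and regulators of the unfolded protein response (nearest 6.64). DMSO 3, with the same number, lay lowest for HSP90AA1 (624 CPM, nearest 1100), for DNAJB11 (65.5, nearest 86.1) and for the mean of cytosolic heat shock genes (5.62, nearest 6.22). Tunicamycin 1 lay lowest for INSR (122 CPM, nearest 138) and for the means of the excitability list (5.60, nearest 5.81) and of NRF2 targets (4.43, nearest 4.81).

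The remaining 5 are spread over other samples. Tunicamycin 2 was lowest for CAPN6 (0.317 CPM, nearest 2.93), DMSO 4 for ALG5 (20.2, nearest 25.5) and DMSO 6 for CRYBA2 (335, nearest 628). DMSO 1 was highest for SOX2 (42.0, nearest 19.1) and tunicamycin 6 for EEF1D (14.2, nearest 4.74).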

How the results depend on the processing

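The fit without both samples numbered 1 and the fit with the mesenchymal mean as a covariate were chosen after seeing the data. In the 25 alternatives run on genes, 0 of the 76 called named genes changed sign, and 64 kept their call in all except the fits of a single batch. Batch 1 alone lost 49 of the 76 calls and batch 2 alone 13. Over all named genes, 2371 comparisons stayed on their side of the threshold, 141 lost and 13 gained a call. For gene lists these numbers were 667, 23 and 12.

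Counts of changed genes moved more than single genes did. DESeq2 called 2100 genes, 1007 of them lower. The replicate block called 2967, 1528 higher and 1439 lower. Batch 1 alone gave 57 (51 higher, 6 lower) and batch 2 alone 654 (449 higher, 205 lower), where fewer samples were tested. Stricter thresholds left 411 genes at 2-fold or more and 580 at an adjusted p under 0.01 (404 higher, 176 lower). The mesenchymal covariate left 366 lower genes, and an estimated correlation left 8 lists. Fry left 13 of the 17 lists and ended the calls of secretory granules (adjusted p = 0.238), mesenchymal cells (0.375), oxidative phosphorylation (0.099) and ribosomal proteins (0.396). The cause was not tested for DESeq2, the block and the covariate. With 1 sample left out, the count of changed genes ran from 791 to 1399, that of higher genes from 514 to 845, that of lower genes from 277 to 603, that of lists from 15 to 18, and that of interaction genes from 0 to 0. Tunicamycin 4 gave the lowest of each gene count.

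Both reversals of a list called in either fit came with the mesenchymal covariate, while 62 other sign changes concerned genes or lists called in neither fit. The sterol list went from 0.0014 to -0.20 (adjusted p = 0.0019), for which the cause was not tested. The test of the mesenchymal list turned up (median -0.15, adjusted p = 0.751), which the covariate's own construction accounts for, since it is the mean of that list. The replicate block changed the calls of TOP2A, HSP90AA1, FTL, DENND2B (adjusted p = 0.0339, against 0.0510) and the proliferation list, and of no other named gene or list. DENND2B was also called with RLE, upper quartile, DESeq2, a filter of 1 CPM in 6 samples and without DMSO 5 or tunicamycin 6 (0.0137 to 0.0447), and MTRR without DMSO 3 (0.0474) and in batch 2 alone (0.0319). On simulated data without pairs the main test recovered 43.3% of changes of 1.5-fold, and the interaction test 4.5% of differences of 2-fold and 72.7% of those of 4-fold.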

Other observations

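The 7 gene lists described first were drawn up after seeing the data, and the tests of shared library differences, of a higher alpha cell share and of BMP-SMAD targets without ID1 and ID3 were chosen after their results or related values were seen. FOXO target genes, which are induced when insulin signalling is low, had 7 of 18 members higher and 0 lower with tunicamycin, against 9 and 1 both adjusted over the list alone and with the block (median 0.38, camera adjusted p = 3.6e-08 over the 7 lists, 0.0237 with an estimated correlation). DEPP1 rose by 2.47, from 64.3 CPM, PDK4, which restrains glucose oxidation, by 1.91, from 125 CPM, and the insulin receptor substrate gene IRS2 by 1.28. INSR, already described, belongs to this list. Interferon-stimulated genes had 6 of 21 members higher and 0 lower, against 11 and 0 with the block (median 0.61, adjusted p = 3.01e-06, 0.0776 with an estimated correlation), among them IFIT1 (1.09), OAS1 (1.74) and IRF9 (0.64). ERK feedback genes had 1 of 12 higher, ETV5 (0.69), and 0 lower, against 3 and 1 with the block (median 0.26, adjusted p = 0.0684).

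Notch targets had 0 of 9 members higher and 4 lower (median -0.73, adjusted p = 0.0011, 0.192 with an estimated correlation), with HEY1 at -1.09, HEY2 at -1.17, HEYL at -1.04 and HES1 at -0.86. WNT targets had 0 of 10 higher and 2 lower, APCDD1 (94.1 to 47.2 CPM) and LGR5 (-2.20), with a median of -0.24 (adjusted p = 0.0117, 0.192 with an estimated correlation). Heart muscle genes marked some cultures. MYH6, the atrial myosin heavy chain gene, reached 199, 175 and 713 CPM in DMSO 1, 4 and 5, against 1.76, 56.3 and 443 CPM in the tunicamycin samples of those numbers, and was at most 12.5 CPM in the other 6. The median of that list was -2.43 (adjusted p = 0.0485, 0.499 with an estimated correlation), with 0 of 10 members called, against 0 higher and 2 lower with the block.

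Target genes of BMP-SMAD signalling were listed after ID1 and ID3 were seen among the largest changes, so the list test is not independent evidence. Of 13 members 0 rose and 6 fell, namely ID1 (-4.02), ID3 (-2.99), ID2 (-1.91), SMAD6 (-1.74), SMAD9 (-1.04) and SMAD7 (-0.54), and 7 did not pass (median of all 13 -0.54, adjusted p = 1.31e-13, 0.0237 with an estimated correlation). Without ID1 and ID3, 4 of 11 fell (median -0.44, adjusted p = 2.5e-07, 0.0484 with an estimated correlation). All 6 decreases stayed called with the mesenchymal mean as a covariate. That mean is an imperfect measure of the number of mesenchymal cells, since its member TAGLN rose by 1.32. The fit therefore does not exclude a loss of mesenchymal cells as the cause. Each of the 6 was lower in 6 of 6 pairs, while the mesenchymal mean was higher in pair 5 (0.16). The median of the 6 was -1.642 (SE 0.223) with the covariate, against -1.83 (SE 0.220) before. These 6 were picked because they fell, and the median of all 13 went from -0.54 to -0.31. The mesenchymal list went from -1.09 to -0.15, which the covariate's own construction accounts for. A trend with gene length, GC content and expression, whose SD over all genes was 0.093, left -1.794.

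Marker lists of mesenchymal, liver and gut, and ductal and acinar cells had lower means with tunicamycin in 5, 6 and 5 of the 6 pairs, with mean differences of -0.95, -0.94 and -0.85. Of 16 mesenchymal markers 0 were called lower without the block and 11 with it. Mesenchymal markers were higher in pair 5 (0.16) and ductal and acinar markers in pair 6 (0.12), and the 3 list calls were lost with an estimated correlation (adjusted p = 0.740, 0.0533 and 0.0533). The 7 lists of other cell types moved apart within pairs (exact sign-flip permutation p = 0.03125, the smallest that 6 pairs allow), with beta cells at -0.40 ± 0.16, delta, PP and epsilon cells at -0.25 ± 0.24, enterochromaffin cells at -0.18 ± 0.18 and pluripotent cells at -0.18 ± 0.29 (SD over 6 pairs). Expression of some markers in alpha cells would also make the lists differ, so a higher share of alpha cells and changes in single cell types cannot be told apart here. Lower expression per cell stays open too, as bulk counts do not separate it from fewer cells. The alpha cell identity list was not called higher (median -0.10, camera adjusted p = 0.241), with 11 members above 0 and 14 below.

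Lists of oxidative phosphorylation and ribosomal protein genes had medians slightly below 0, and both calls were lost with an estimated correlation. Lists matched on gene length, GC content and expression level had medians of 0.009 and 0.004. Each real median lay at percentile 0 of 10000 matched lists (-0.26 against -0.07 to 0.09, and -0.19 against -0.07 to 0.08, the central 95% of matched lists). How close the matches were was not checked. Matched genes were drawn independently, while genes of the 2 lists vary together (estimated correlations 0.58 and 0.79). The percentile therefore does not decide whether a trend with these properties contributes. Differences between libraries that the genes of the list share may account for the ribosomal shift, which was negative in 3 of 6 pairs (exact sign-flip permutation p = 0.375; adjusted p = 0.740 with an estimated correlation). For oxidative phosphorylation the shift was negative in 6 of 6 pairs (mean -0.24, exact p = 0.03125, the smallest possible) but not called with an estimated correlation (adjusted p = 0.529), so such differences and an effect of the drug cannot be told apart. The rule that weighs these values was set after they were seen.

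Other groupings of the samples were compared with the real one over 100 of the 200 splits balanced over batches. For the 1344 changed genes 1 of 100 splits, the real one, gave as many and the highest other gave 0. Among the other splits, 18 part all 6 pairs as the real one does and 81 part fewer, and the highest count in each set was 0. The 18 are too few for a share under 0.05. Every other split holds samples of both groups on each side, so the treatment difference adds to the spread it is tested against. Splits that share 10 of the 12 samples with the real one or its mirror also gave 0, so these counts do not exclude chance. For the 17 lists that moved at the preset correlation the splits do not exclude chance, since 19 of 100 gave as many and the highest other gave 22 lists. They cannot show that chance gave the 17 either, because splits that resemble the real one hold part of the treatment difference. Splits with 22 lists shared 8 or 10 of the 12 samples with the real grouping or its mirror. Those that shared 6 have equal numbers of both groups on each side, over both batches together. They moved between 3 and 15 lists, so lists were called at the preset correlation without a net treatment difference. The splits that part all pairs reached 20 lists, and all splits other than the real one had a median of 12. With an estimated correlation, a comparison made in addition, the real split gave 8 lists and the highest other 1. In the other splits the treatment difference stays in the spread from which the correlation is estimated. This contrast therefore does not exclude chance either. For the batch comparison all 10 ways to divide the 6 pairs gave 0 genes, the real division included, and 10 splits are too few for a share under 0.05.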
